A study of Rattus norvegicus with 12 samples.

How the data were processed

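Total RNA was extracted with a phenol-based kit from hearts of male Sprague Dawley rats, 5 weeks old and 130 to 150 g at the start, and sequenced on an Illumina NextSeq 500 as 12 libraries, per the labels' protocols. The labels place 4 libraries in each of 3 groups: CTRL, SU_HX (SU-5416 at 20 mg/kg, 3 weeks at 10% oxygen, 2 weeks of normoxia, 3 weeks of vehicle) and Chrysin (the same with chrysin at 100 mg/kg per day). Groups and rat numbers were taken from the labels and never from the values.

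The authors deposited a single table of 32623 genes and 310 columns. Per the file headers, each library has an expression value, which is a whole-number count per gene, together with exon reads, intron reads and reads unique to the gene. In every gene and library the deposited count lay between the unique and the total exon reads. The aligner, its version, the genome build and the annotation are not given in the sources used here. Gene starts in the table were found to count from 0, by comparing exon length with start and end in 3157 genes of 1 exon and 1 transcript, and 1 was added to each start printed. The authors' table also holds their own test of each pair of groups, per the file headers an empirical analysis of digital gene expression with tagwise dispersions: p-values with and without adjustment for the false discovery rate, and signed fold changes, a score in which a fall is a negative number. These were used only to set the authors' calls beside those made here. The intron and unique read columns served for checks of the libraries and of gene copies.

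All 12 libraries had counts that differed beyond sampling noise within each group (smallest chi-square per degree of freedom 3.31), so each was counted once. Of the genes, 14175 had 0 counts in all libraries. A symbol that occurs more than once carries a copy number, as in Cttn_1 (4516 such genes). Total counts per library had a median of 5085570; the lowest was 3997306 and the highest 6009798. A count of 0 over a group was given a floor of 3 counts over that group, which covers counting error only.

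The main test was edgeR's quasi-likelihood F test (edgeR 4.0.16, R 4.3.3; TMM factors, filterByExpr by group, robust fit) on the deposited counts, with all 12 libraries in 1 fit that shares the estimate of the spread, and Benjamini-Hochberg adjustment with a threshold of 0.05; it is two-sided. The filter left 12304 genes. CPM values are counts per unit of TMM-scaled library total, set to the usual CPM scale; log2 CPM values use a prior count of 2. Gene lists for pathways and cell types were tested with camera (limma 3.58.1) with a preset correlation of 0.01, for lists with at least 5 measured members, adjusted over all lists and the 3 comparisons together; 44 lists were tested. Camera was also run with an estimated correlation, and fry as a test of each list alone. Mean log2 CPM of a list per rat was compared by an exact permutation test (smallest two-sided p 0.0286).

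Opposite changes were counted among genes changed in SU_HX. Because comparisons share libraries, 100 simulated unchanged groups, independent lists and split groups gave the values set beside them. In the simulations the shared group was drawn anew together with the unchanged ones, around 1 mean per gene, so that both comparisons shared its error. The share of the SU_HX change opposed in Chrysin rats was computed from subsets of the groups that share no library: minus the covariance over genes of SU_HX minus CTRL with Chrysin minus SU_HX, divided by the covariance of the SU_HX change between such subsets. Its p is a one-sided exact permutation over rats.

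Genes named in the text follow a rule. For SU_HX against CTRL, and for Chrysin against SU_HX, it takes the 8 largest rises and 8 largest falls among genes with an official symbol, an adjusted p under 0.05, a mean of at least 1 CPM and no overlap between the groups' values. Where fewer than 5 pass in a direction, the 5 lowest p are given as values that did not pass. For Chrysin against CTRL it takes 5 in each direction. A set of preset genes of the heart, of matrix, of VEGF and BMP signalling and of xenobiotic metabolism is given in each comparison, with up to 4 members with the smallest p of each list described, of which 2 were taken; the rule takes 127 genes, and 102 of them are named or drawn on in the text. Where 5 or fewer members of a list passed in a direction they are named too, except for a few that are not reported here; 53 genes named for this reason, or because they passed under another setting, were chosen after their values were seen, as were Lyve1 and Ccl5. The groups, tests, lists, this rule and the alternatives listed next were fixed before the data were examined.

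The alternatives were relative-log size factors, no filter, a mean of at least 5 CPM, DESeq2 1.42.0, limma-voom, only the groups compared, rat number as a block, each of the 12 libraries left out in turn, a fold of at least 2, an estimated correlation and fry. Chosen after seeing the data were SU_HX rat 1 and Chrysin rat 3 left out together, reads unique to 1 gene, all exon reads, voom with quality weights, copies of a symbol summed, and each SU_HX and Chrysin library left out for the alpha-globin copies. Pseudocounts were not varied, since the table holds counts. The test was checked on simulated counts with known changes: in SU_HX against CTRL it recovered 10.4, 47.8 and 89.4% of genes changed 1.5-, 2- and 4-fold, with 4 false calls. In Chrysin against SU_HX it recovered 7.46, 41.8 and 90.9%, with 6 false calls, and in Chrysin against CTRL 7.46, 47.8 and 92.4%, with 6. DESeq2 gave 28, 13 and 18 false calls. The simulated genes were drawn independently, with 1 spread per gene for all groups, so recovery in the real libraries may differ. Tables were read with data.table (version 1.17.8) and figures drawn with Python 3.11.15 and matplotlib 3.10.9.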

Results

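RNA from the hearts of male Sprague Dawley rats was sequenced in 12 libraries, which the labels place in 3 groups of 4. CTRL rats were kept in normoxia for 8 weeks. SU_HX rats received SU-5416, a blocker of the VEGF receptors, at 20 mg/kg and spent 3 weeks at 10% oxygen and 2 weeks in normoxia, followed by 3 weeks of vehicle; the order of the hypoxic and normoxic weeks is ambiguous in the labels. This combination is a rat model of pulmonary hypertension, in which the right side of the heart pumps against a raised pressure. Chrysin rats received the same model and then chrysin, a plant flavone, at 100 mg/kg per day for 3 weeks. The region of the heart is not stated. The labels do not say outright that each library came from a separate rat, so p-values measure the spread between these samples. Total counts per library ran from 4712077 to 5443100 in CTRL, from 4036489 to 5797763 in SU_HX and from 3997306 to 6009798 in Chrysin. Values are CPM (counts scaled to a common library total) as mean ± SD with n = 4 per group. Log2 fold changes carry an approximate standard error (SE). It is the absolute log2 fold change divided by the square root of the F statistic of its test. The p-values are two-sided. Positions are those in the deposited table, with the genome build not given in the sources used here.

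The first principal component, with 52.8% of the variance, set the 4 CTRL rats (-54.0 to -46.6) and Chrysin rat 3 (-31.3) apart from the other 7 model rats (15.2 to 60.6). The second, with 18.2%, was highest in SU_HX rat 1 (70.0). In SU_HX rat 1, 63.4% of the uniquely mapped reads on nuclear genes lay in introns, against 42.6 to 50.0% in the other libraries. Chrysin rat 3 had Nppa at 119.9 CPM, whereas the other 7 model rats lay between 1293 and 7084 CPM.

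The comparison of SU_HX with CTRL asked what the disease model did to the heart. Hearts of SU_HX rats carried high levels of natriuretic peptide transcripts, of matrix genes and of xenobiotic-metabolising enzymes. Their transcripts for the fast myosin heavy chain, the calcium pump of the sarcoplasmic reticulum and mitochondrial fuel oxidation were low. Of 12304 genes tested, 1965 rose and 1811 fell (3776 at an adjusted p under 0.05 by edgeR's quasi-likelihood test). Of 44 gene lists camera called 14 higher and 6 lower (20), and 0 with an estimated correlation. Fry, which tests each list on its own, called 25, with 18 of them among these 20. By the exact permutation test of list means per rat the smallest p was 0.0286 (not adjusted), the lowest that test can give. Of the genes called, 1016 rose and 884 fell by at least 2-fold (1900). Without SU_HX rat 3 the count was 2486. The authors' deposited table lists 3205 genes at an adjusted p under 0.05 for this comparison, 2948 of them called here as well.

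Genes of the cardiac stress response rose together. Nppa (ENSRNOG00000008176; chromosome 5, 164808323 to 164809705, 3 exons), the gene of atrial natriuretic peptide, stood at 3935 ± 1889.9 against 16.7 ± 8.96 CPM, a 235-fold rise (log2 7.88, SE 1.07, adjusted p = 0.000992). Nppb, which encodes the B-type peptide, rose 11.7-fold to 496 ± 247 CPM (adjusted p = 0.000992), and Ankrd23, an ankyrin repeat protein of the sarcomere, 25.5-fold to 154 ± 90.3 CPM (adjusted p = 0.000992). Acta1, skeletal alpha-actin, rose 5.51-fold (adjusted p = 0.00192). Myh7, the slow beta-myosin heavy chain, rose 3.56-fold to 15399.6 ± 5393 CPM (adjusted p = 0.00467). Of the 24 measured cardiac stress genes, 18 rose, 0 fell and 6 did not pass; adjusted over the list alone, 18 rose. The list was called higher by camera (adjusted p = 2.72e-09), but not with the correlation of its members taken from the data (adjusted p = 0.468 with an estimated correlation). SU_HX rat 1 had the lowest mean of this list among SU_HX rats, 0.71 log2 above CTRL, with the other 3 at 2.02 to 2.49. In SU_HX the atrial markers, Nppa included, averaged 0.68 log2 from CTRL (0.22 to 1.40) and skeletal muscle markers 0.66 (0.23 to 1.03). Ventricular markers averaged -0.13 (-0.83 to 0.59). Camera called none of these lists, and the region of the heart is not stated.

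Adult contractile and conduction genes went the other way. Myh6 (ENSRNOG00000025757; chromosome 15, 33605654 to 33629699, 38 exons), the fast alpha-myosin heavy chain, stood at 4009.5 ± 2348 against 40499.9 ± 2549 CPM (log2 -3.34, SE 0.77, adjusted p = 0.00705). Myh6 and Myh7 lie in a near-identical pair and 79.4% and 75% of their exon reads mapped to 1 gene alone, so how reads were divided between them is uncertain. Atp2a2 (ENSRNOG00000001285; chromosome 12, 39553903 to 39603326, 23 exons), the calcium pump SERCA, stood at 4809.7 ± 2831 against 16414 ± 575 CPM (log2 -1.77, adjusted p = 0.00754). Trdn, a triadin of the calcium release complex, and Cacna1c, the L-type calcium channel, had log2 changes of -1.61 (adjusted p = 0.00346) and -1.05 (adjusted p = 0.00506). Of 24 genes for adult contraction and calcium handling, 12 fell, 0 rose and 12 did not pass (12 fell adjusted over the list alone; camera adjusted p = 3.22e-06, and adjusted p = 0.529 with an estimated correlation). Of 21 cardiac ion channel and gap junction genes, 11 fell, 1, the T-type calcium channel Cacna1g (2.74 log2, adjusted p = 0.00260), rose and 9 did not pass (adjusted over the list alone, 12 fell and 1 rose; camera adjusted p = 0.000333, and adjusted p = 0.468 with an estimated correlation). Among them, the potassium channels Kcnj3 and Kcnh2 changed by -2.39 (SE 0.39) and -1.80 (SE 0.29) log2, with adjusted p = 0.00151 and 0.00150. SU_HX rat 1 was lowest for the contractile list (-1.66 log2 from CTRL) and SU_HX rat 2 highest (-0.48).

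**Figure D1:**
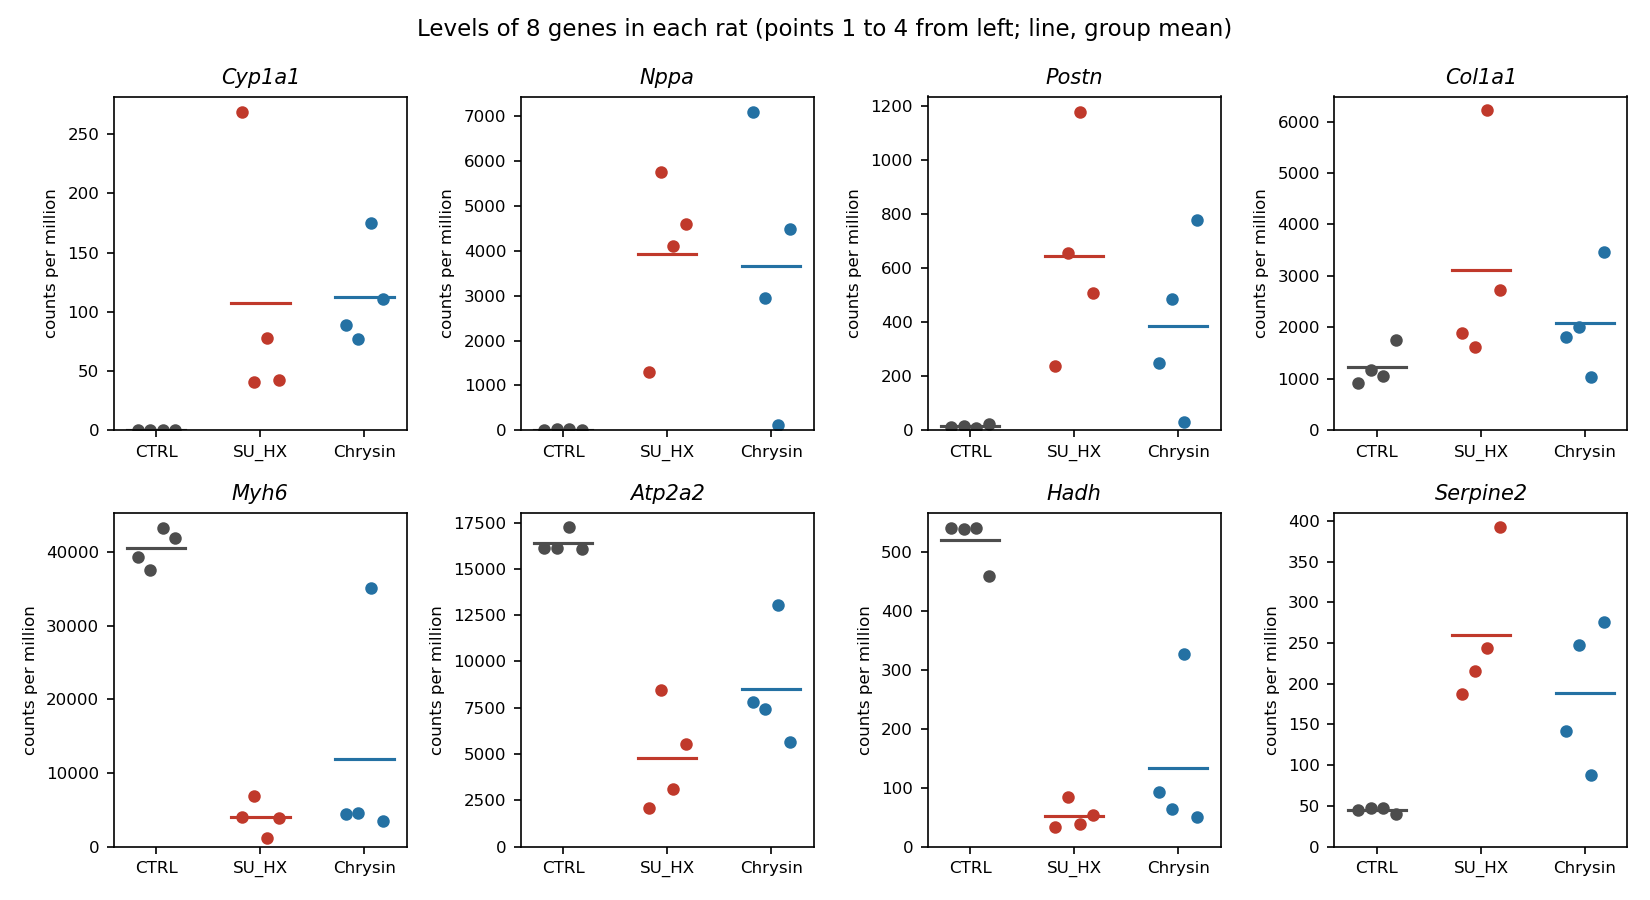
Level of 8 genes in each rat, in CPM on linear axes from 0, by group (CTRL, SU_HX, Chrysin), with a point per rat and a line at the group mean. Cyp1a1 was at 0 in the CTRL rats and between 40.9 and 268 CPM in the model rats; Chrysin rat 3 had Myh6 at 35113 CPM and Postn at 29.4 CPM.

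Matrix genes rose broadly. Thbs4 (ENSRNOG00000012471; chromosome 2, 22343727 to 22385855, 25 exons), a thrombospondin of the matrix, stood at 328 ± 141 against 1.55 ± 1.17 CPM (log2 7.69, SE 1.07, adjusted p = 0.000992). Postn (ENSRNOG00000012660; chromosome 2, 143656793 to 143688087, 24 exons), periostin, a protein of activated fibroblasts, stood at 644 ± 394 against 14.8 ± 5.78 CPM (log2 5.44, adjusted p = 0.00124). Ltbp2, a latent TGF-beta binding protein, rose by 5.71 log2 (adjusted p = 0.00151), and Comp, a cartilage matrix protein, by 5.55 (adjusted p = 0.00205). Of 43 genes for fibrillar collagen and extracellular matrix, 37 rose, 0 fell and 6 did not pass (39 rose adjusted over the list alone; camera adjusted p = 3.81e-16, and adjusted p = 0.468 with an estimated correlation). Col1a1 and Col3a1, the main fibrillar collagens, rose 2.55-fold (adjusted p = 0.0381) and 2.56-fold (adjusted p = 0.0300). Both calls were fragile: Col1a1 was not called without CTRL rat 1, 2 or 3, Chrysin rat 1 or 2, or SU_HX rat 3 or 4 (adjusted p between 0.0515 and 0.171), and Col3a1 not without CTRL rat 1, 2 or 3 or SU_HX rat 3 (0.0715 to 0.134) or with only these 2 groups in the fit (0.0571).

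Serpine2 (ENSRNOG00000015461; chromosome 9, 85560863 to 85626094, 11 exons), a serine protease inhibitor, rose 5.76-fold to 259.9 ± 91.4 CPM (adjusted p = 0.000958), and Timp1, an inhibitor of matrix metalloproteinases, 14.1-fold (adjusted p = 0.00114; 76.2% of its exon reads were unique). Of 19 matrix proteases and inhibitors, 12 rose and 2 fell (14 and 2 adjusted over the list alone; camera adjusted p = 6.38e-05, and adjusted p = 0.484 with an estimated correlation). Those that fell were the proteases Adamts15 (-1.02 log2) and Adamts12 (-0.56). Adamts15 was not called without CTRL rat 2 or 4 (adjusted p from 0.0543 to 0.0688), and Adamts12 not without CTRL rat 3 or 4 or SU_HX rat 2 or 4 (0.0529 to 0.0997); with only these 2 groups in the fit neither was called (0.0556 and 0.0501). Of 21 genes of the TGF-beta pathway, 13 rose and 1 fell (15 and 1 adjusted over the list alone; camera adjusted p = 5.48e-05, and adjusted p = 0.468 with an estimated correlation). The ligands Tgfb2 and Tgfb1 rose 11.8-fold (adjusted p = 0.000895) and 2.30-fold (adjusted p = 0.00101), and the co-receptor Tgfbr3 fell (-0.71 log2, adjusted p = 0.00286). Of 16 fibroblast markers, 10 rose and 0 fell (10 adjusted over the list alone; camera adjusted p = 0.00134, and adjusted p = 0.527 with an estimated correlation). They included Fap, a surface protease of activated fibroblasts (4.17-fold, adjusted p = 0.00145), and the microfibril gene Mfap5 (3.58-fold, adjusted p = 0.00229). Of 14 basement membrane genes, 5 rose and 0 fell (5 adjusted over the list alone; camera adjusted p = 0.0119, and adjusted p = 0.529 with an estimated correlation). They were the laminins Lama5 (2.78-fold, adjusted p = 0.00207), Lamc1 (2.18-fold) and Lamb1 (1.67-fold) and the collagens Col4a1 (2.35-fold, adjusted p = 0.00631) and Col4a2 (1.91-fold). Lamb1 was not called without CTRL rat 3 (0.0503), nor Col4a2 without CTRL rat 1, 2 or 3 or SU_HX rat 3 (0.0540 to 0.0651). SU_HX rat 3 had the highest mean of the matrix list (2.76 log2 above CTRL), with the other SU_HX rats at 1.53 to 1.91.

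Genes of mitochondrial fuel use fell. Hadh (ENSRNOG00000010697; chromosome 2, 236353445 to 236395067, 8 exons), an enzyme of fatty acid beta-oxidation, stood at 52.5 ± 23.1 against 521 ± 40.3 CPM (log2 -3.31, SE 0.54, adjusted p = 0.00150), and Decr1, a reductase for unsaturated fatty acids, changed by -1.72 log2 (adjusted p = 0.00149). Of 33 fatty acid oxidation genes, 29 fell, 0 rose and 4 did not pass (30 fell adjusted over the list alone; camera adjusted p = 1.87e-16, and adjusted p = 0.468 with an estimated correlation). Of 49 nuclear genes for oxidative phosphorylation, 35 fell and 0 rose (45 fell adjusted over the list alone; camera adjusted p = 3.47e-14, and adjusted p = 0.527 with an estimated correlation). Examples were Ndufs7 of complex I (-1.20 log2, adjusted p = 0.00510) and the ATP synthase subunit Atp5c1 (-1.52, adjusted p = 0.00617). Of 20 tricarboxylic acid cycle genes, 15 fell and 0 rose (17 adjusted over the list alone; camera adjusted p = 4.09e-08, and adjusted p = 0.527 with an estimated correlation), with Sdhd of succinate dehydrogenase at -1.52 log2 (adjusted p = 0.00739) and the succinyl-CoA ligase Suclg2 at -1.13 (adjusted p = 0.00778). Of 19 genes for the breakdown of ketone bodies and branched-chain amino acids, 16 fell and 0 rose (18 adjusted over the list alone; camera adjusted p = 1.86e-10, and adjusted p = 0.468 with an estimated correlation). Bcat2, the mitochondrial branched-chain aminotransferase, changed by -1.86 log2 (adjusted p = 0.00114), and Bckdk, a kinase of the next enzyme of that pathway, by -1.67 (adjusted p = 0.00160). SU_HX rat 1 was lowest for fatty acid oxidation (-1.96 log2 from CTRL) and oxidative phosphorylation (-2.19), where the other SU_HX rats lay at -1.53 to -1.17 and -1.35 to -0.39.

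Targets of the aryl hydrocarbon receptor, a sensor of foreign compounds, rose. Cyp1a1 (ENSRNOG00000019500; chromosome 8, 62472095 to 62478147, 7 exons), its classic target, had 0 counts in all 4 CTRL rats and 108 ± 109 CPM in SU_HX, at least 707-fold higher against a floor of 3 counts over the CTRL group (adjusted p = 0.000956). Cyp1b1 (ENSRNOG00000040287; chromosome 6, 2307808 to 2316722, 9 exons) stood at 413 ± 139 against 14.2 ± 3.33 CPM (log2 4.87, SE 0.40, adjusted p = 0.000183). Of 8 targets, 5 rose and 0 fell (5 adjusted over the list alone; camera adjusted p = 8.19e-05, and adjusted p = 0.468 with an estimated correlation). Besides both enzymes, they were the receptor's repressor Ahrr (5.20 log2, adjusted p = 0.000992), the quinone reductase Nqo1 (0.72, 0.0131) and the receptor gene Ahr itself (0.71, 0.0416). Ahr was not called without CTRL rat 2, 3 or 4, Chrysin rat 2 or SU_HX rat 1 or 3 (adjusted p from 0.0524 to 0.128), nor by limma-voom, with only these 2 groups in the fit, with voom quality weights or without SU_HX rat 1 and Chrysin rat 3 (0.0610 to 0.144).

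Complement, macrophage and cytokine genes also rose, whereas lists of T and NK cell markers (camera adjusted p = 0.378) and of interferon-stimulated genes (0.0547) were not called. Of 18 complement genes, 15 rose and 0 fell (16 adjusted over the list alone; camera adjusted p = 6.85e-10, and adjusted p = 0.468 with an estimated correlation), among them the subunit gene C1qc (3.86-fold, adjusted p = 0.00108) and the receptor gene C5ar1 (3.24-fold, adjusted p = 0.00112). Of 15 macrophage and monocyte markers, 13 rose and 0 fell (adjusted over the list alone, 14 rose and 1, Lyve1, fell; camera adjusted p = 1.73e-07, and adjusted p = 0.468 with an estimated correlation). Aif1, a macrophage marker, rose 3.63-fold (adjusted p = 0.00118) and the Fc receptor Fcgr1a 6.17-fold (adjusted p = 0.00119). Of 25 cytokine and chemokine genes, 12 rose and 1, Cxcl11, fell (adjusted over the list alone, 14 and 2, with Ccl5 as the other; camera adjusted p = 0.000613, and adjusted p = 0.468 with an estimated correlation). Csf1, a growth factor of macrophages, rose 2.38-fold (adjusted p = 0.00114) and Sele, an endothelial adhesion molecule, 4.23-fold (adjusted p = 0.00115).

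Markers of blood and lung moved with the model. All 7 measured erythroid markers rose (7 adjusted over the list alone; camera adjusted p = 3.82e-05, and adjusted p = 0.468 with an estimated correlation). The alpha-globin copies Hba-a2_1 and Hba-a2_2 rose 9.12-fold and 7.63-fold (adjusted p = 0.00421 and 0.00442); only 60.9% and 61.0% of their exon reads were unique, so the division between them is uncertain. Of 5 lung epithelial markers, 4 rose and 0 fell (4 adjusted over the list alone; camera adjusted p = 0.0113, and adjusted p = 0.468 with an estimated correlation; 0.0646 without SU_HX rat 1 and Chrysin rat 3). Scgb1a1, a secretory protein of airway cells, stood at 10.3 ± 8.92 against 0.198 ± 0.157 CPM (adjusted p = 0.00350) and the surfactant gene Sftpa1 at 4.32 ± 3.04 against 0.240 ± 0.480 CPM (adjusted p = 0.00717). The surfactant gene Sftpc (4.12 log2, adjusted p = 0.00749) and the protease Napsa (1.75, 0.0351) also rose, Napsa not without any 1 of the CTRL rats or SU_HX rat 3 (0.0603 to 0.125), nor by limma-voom (0.0770). Of 61 cytosolic ribosomal protein genes, 8 rose and 0 fell (1, Rpl3, adjusted over the list alone), with Rpl3 up 2.96-fold (adjusted p = 0.00151); camera called the list (adjusted p = 0.00796, and adjusted p = 0.764 with an estimated correlation), but not without SU_HX rat 3 (0.210), and fry did not (0.221). For 32 cell cycle genes camera gave an adjusted p of 0.0499 (adjusted p = 0.776 with an estimated correlation), with 0 members passing, over all genes or adjusted over the list alone, by edgeR. DESeq2 called the kinesins Cenpe and Kif23 (0.0234 and 0.0331) and limma-voom 0. In edgeR 8 members passed without SU_HX rat 2 and 7 without SU_HX rat 4 (adjusted p from 0.0199 to 0.0447), Cenpe without Chrysin rat 3 (0.0450), and Anln, a scaffold of cell division, without Chrysin rat 4 (0.0474) or with all exon reads counted (0.0234); only 29.2% of its exon reads were unique, so its value is uncertain. With voom quality weights Aurka, Mcm4 (75% of exon reads unique) and Melk passed (0.0286 to 0.0440). The camera call was absent without CTRL rat 1, 2 or 3, Chrysin rat 3 or 4, or SU_HX rat 1 or 3 (adjusted p between 0.0511 and 0.429), without SU_HX rat 1 and Chrysin rat 3 together (0.458) and by fry (0.315).

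Other large rises were those of Fgf23 (ENSRNOG00000052205; chromosome 4, 159622404 to 159630082, 3 exons), a phosphate-regulating hormone with 0 counts in CTRL and 3.41 ± 0.478 CPM in SU_HX (at least 22.5-fold higher, adjusted p = 0.00145), of Olr1, a receptor for oxidised lipoprotein (5.76 log2, adjusted p = 0.00230; 0.0598 by limma-voom), and of C1qtnf3 (at least 61.5-fold higher, adjusted p = 0.0194). C1qtnf3 stood at 31.3 CPM in SU_HX rat 3 and at 0.696 to 4.16 in the others, and was not called by limma-voom (adjusted p = 0.0638) or without the filter on low counts (0.0612). The largest falls were those of Gabrb2 (ENSRNOG00000003680; chromosome 10, 27973681 to 28187565, 10 exons), a GABA receptor subunit, from 16.8 ± 4.22 to 0.337 ± 0.382 CPM (log2 -5.43, adjusted p = 0.000992), and of Atp6ap1l (-5.36, adjusted p = 0.00106). Then came Art1, Dhrs7c, Cacng6, Myo16 and Crybb1, with log2 changes of -5.17, -4.96, -4.61, -4.51 and -4.42. The chemokine Cxcl11 was also among them (-4.37, adjusted p = 0.00553), but only 28.5% of its exon reads were unique and its value is uncertain. Of the genes tied to the model drug and to the heritable form of the disease, the VEGF receptor Kdr rose 1.66-fold (adjusted p = 0.0429) and the BMP receptor Bmpr2 1.34-fold (adjusted p = 0.0481). Kdr was not called without any 1 of the 4 CTRL rats, Chrysin rat 1 or 2 or SU_HX rat 1 (adjusted p between 0.0570 and 0.102), nor by limma-voom, without the filter on low counts, with only these 2 groups in the fit, with voom quality weights or without SU_HX rat 1 and Chrysin rat 3 (up to 0.0820). Bmpr2 was not called without any 1 of the 11 libraries other than SU_HX rat 1 (0.0534 to 0.137), nor with relative-log size factors, all exon reads, no filter or only these 2 groups in the fit (0.0552 to 0.134). Vegfa, the ligand, stood at 629 ± 239 against 603 ± 48.0 CPM (adjusted p = 0.865).

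**Figure D2:**
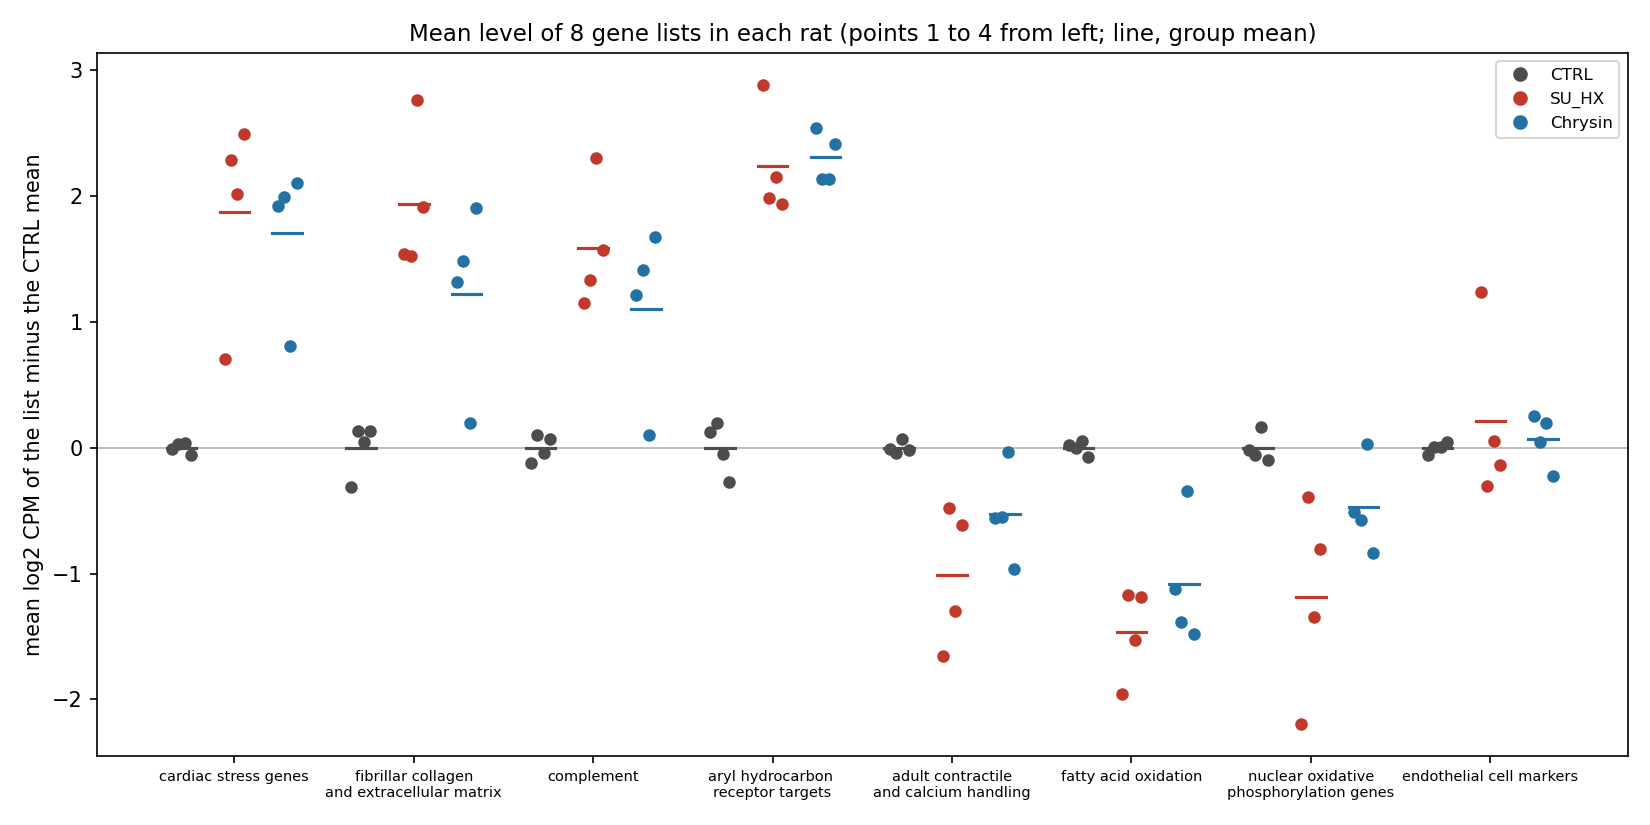
Mean log2 CPM of the members of 8 gene lists in each rat, minus the CTRL mean, by group, with a point per rat and a line at the group mean. For fatty acid oxidation the SU_HX rats lay between -1.96 and -1.17, and Chrysin rat 3 at -0.34; for aryl hydrocarbon receptor targets Chrysin rat 3 lay at 2.14, within the range of the other model rats.

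The comparison of Chrysin with SU_HX asked what the flavone did in hearts already carrying the disease model. No single gene differed past the threshold. Metabolic and contractile lists had higher means in Chrysin rats and matrix and interferon lists lower means, and of the lists called by camera none passed a two-sided exact permutation test of the means per rat (smallest p = 0.0571, not adjusted). Nppa stood at 3656 ± 2912 against 3935 ± 1889.9 CPM (adjusted p = 0.963) and Myh6 at 11876 ± 15499 against 4009.5 ± 2348 CPM (adjusted p = 0.557). Of 12304 genes, 0 passed edgeR's quasi-likelihood test (smallest adjusted p = 0.461), 1002 had an unadjusted p under 0.05, and limma-voom called 0. DESeq2 called 2, Cttn_1 (adjusted p = 0.000676) and Rgs6 (adjusted p = 0.0206). On simulated data the edgeR test recovered 41.8% of genes changed 2-fold and 90.9% of those changed 4-fold in this comparison. Those genes were drawn independently, with 1 spread per gene for all groups. In the real libraries, correlations between replicates ran from 0.979 to 0.983 in CTRL, 0.881 to 0.972 in SU_HX and 0.927 to 0.980 in Chrysin. Recovery here may therefore be lower than simulated.

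The genes with the lowest p are given as values that did not pass. Cttn_1, a copy of the cortactin gene, an organiser of actin filaments, stood at 12.6 ± 3.28 against 32.0 ± 7.19 CPM (log2 -1.33, SE 0.22), and its other copy Cttn_2 at 16.7 ± 3.81 against 3.94 ± 2.66 CPM (log2 2.05, SE 0.50, adjusted p = 0.557). Lower values were also measured for Plekhh2 (log2 -1.05), the globin gene Hba-a3 (-3.55), Angptl4, a lipoprotein lipase inhibitor (-2.76), and the PACAP receptor Adcyap1r1 (-0.77). Higher values were measured for Rgs6 (ENSRNOG00000008082; chromosome 6, 106496992 to 106602139, 17 exons), a regulator of G protein signalling (1.12), and for Ralgps2 (0.89), Shmt2, a mitochondrial enzyme of serine metabolism (0.58), and Trim50 (0.83). Each of the last 8 had an adjusted p of 0.557. For the genes fixed in advance, Cyp1a1 stood at 113 ± 43.7 against 108 ± 109 CPM (adjusted p = 0.966) and Cyp1b1 at 404 ± 178 against 413 ± 139 CPM (adjusted p = 0.975). The log2 values were -0.09 for Nppb, 0.11 for Acta1, 0.06 for Myh7, -0.11 for Vegfa, 0.00 for Bmpr2 and -0.29 for Kdr (adjusted p from 0.641 to 0.994). Atp2a2 had 0.82 (SE 0.41), Timp1 -0.98 (SE 0.46), Postn -0.74 (SE 0.68), Col3a1 -0.76 (SE 0.43) and Col1a1 -0.58 (SE 0.45), with adjusted p from 0.557 to 0.656.

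Camera called 19 of 44 lists, 8 higher and 11 lower in Chrysin; with an estimated correlation it called 0 and fry, which tests a list on its own, also 0 (smallest adjusted p = 0.0741). In each of the 19, 0 members passed over all genes. Adjusted over the list alone, 0 passed as well, apart from 2 lower lung epithelial markers. Those 2 were Scgb1a1 (-2.62 log2, adjusted p = 0.557 over all genes) and Sftpc (-2.27, adjusted p = 0.557). All 49 oxidative phosphorylation genes had positive log2 values (median 0.60; camera adjusted p = 1.11e-20, and adjusted p = 0.468 with an estimated correlation), for example Cox8b of cytochrome oxidase (1.08) and Ndufb10 of complex I (0.86). Tricarboxylic acid cycle genes such as Idh2 (0.82) had higher values (camera adjusted p = 3.87e-11, and adjusted p = 0.468 with an estimated correlation), as had genes for ketone body and branched-chain amino acid breakdown (1.86e-10, and adjusted p = 0.468 with an estimated correlation). The same held for contractile genes (7.71e-07, and adjusted p = 0.527 with an estimated correlation; 0.186 with SU_HX rat 1 and Chrysin rat 3 both left out) and ion channels (9.83e-05, and adjusted p = 0.468 with an estimated correlation). The calls of 3 further higher lists depended on single rats. Fatty acid oxidation genes, with Hadh at 1.33 and their regulator Ppara at 0.76, were called higher (5.33e-06, and adjusted p = 0.530 with an estimated correlation) but not without Chrysin rat 3 (0.0900), and their sign turned with SU_HX rat 1 left out as well (0.441). Glycolysis (7.81e-05, and adjusted p = 0.527 with an estimated correlation) was not called without SU_HX rat 1 (0.0820). Ventricular markers (0.0159, and adjusted p = 0.529 with an estimated correlation) were not called without Chrysin rat 1 or SU_HX rat 1 or 3 (0.0592 to 0.275), nor without SU_HX rat 1 and Chrysin rat 3 together (0.217). Chrysin rat 3 had the highest means of the Chrysin group for oxidative phosphorylation (0.03 log2 from CTRL) and fatty acid oxidation (-0.34), and SU_HX rat 1 the lowest of its group.

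On the lower side, all 43 matrix genes had negative log2 values (median -0.60; camera adjusted p = 1.39e-11, and adjusted p = 0.484 with an estimated correlation), for example the fibrillar collagen Col5a3 (-0.97) and tenascin C, Tnc (-1.75). All 31 interferon-stimulated genes did as well (median -0.41; camera adjusted p = 6.92e-09, and adjusted p = 0.468 with an estimated correlation), with Mx2 at -0.68 and Oas1a, of whose exon reads 72.2% were unique, at -1.07. The mean of the interferon list per rat differed by -0.40 log2 from SU_HX to Chrysin, more than the SD of either group (0.158 in Chrysin and 0.266 in SU_HX), with a two-sided exact permutation p of 0.0571. Of 24 immediate early genes, 23 had negative values, such as the transcription factors Egr3 (-1.85) and Nr4a3 (-0.88; camera adjusted p = 4.81e-07, and adjusted p = 0.484 with an estimated correlation). SU_HX rat 1 had the highest means of its group for both lists (0.67 and 1.27 log2 from CTRL, against 0.03 to 0.27 and -0.32 to 0.17 in the other 3). Matrix proteases (4.79e-06, and adjusted p = 0.468 with an estimated correlation) and lung epithelial markers (0.00806, and adjusted p = 0.468 with an estimated correlation) were also called lower.

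The remaining 6 lower lists lost their call when a rat was left out. Complement (0.000163, and adjusted p = 0.529 with an estimated correlation), macrophage markers (0.000755, and adjusted p = 0.538 with an estimated correlation) and fibroblast markers (0.00488, and adjusted p = 0.529 with an estimated correlation) were not called without Chrysin rat 3 or SU_HX rat 3. Their adjusted p then lay at 0.0618 to 0.0848, 0.0654 to 0.144 and 0.0765 to 0.18. The TGF-beta list (0.000991, and adjusted p = 0.527 with an estimated correlation) was not called without Chrysin rat 3 (0.0765). Mitochondrially encoded genes (0.00606, and adjusted p = 0.618 with an estimated correlation) were not called without Chrysin rat 2 or 4 (0.0618 to 0.114). Basement membrane genes (0.0352, and adjusted p = 0.567 with an estimated correlation) were not called without Chrysin rat 3 or 4 or SU_HX rat 1, 3 or 4 (0.0550 to 0.310), nor without SU_HX rat 1 and Chrysin rat 3 together (0.891).

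Among the 3776 genes changed in SU_HX, 3561 (94.3%) had a Chrysin minus SU_HX value of the opposite sign. Among the genes called without Chrysin rat 3 this share was 82.9%, and without this rat and SU_HX rat 1 it was 80.9%. Both comparisons use the SU_HX rats. With SU_HX and Chrysin groups simulated around the same means, gene by gene, the share averaged 59.8% (57.3 to 62.0% in 100 simulations), and with the SU_HX rats split between the comparisons it averaged 76.8% (65.3 to 91.8%). Of these genes, 0 were called in both directions by edgeR and 2 by DESeq2; by independent lists the overlap would be 0. Over all genes the log2 values of both comparisons had a correlation of -0.69 (simulated mean -0.172, and -0.61 to -0.29 with the SU_HX rats split) and a covariance of -0.240 (simulated mean -0.0498, and -0.220 to -0.0900 with the rats split). The simulated groups leave out the correlation between genes within a rat. The share of the SU_HX change opposed in Chrysin rats, estimated from subsets of rats that share no library, was 27.1% (15.3 to 37.3% over 6 splits of the rats). Of the 70 assignments of the 8 rats to both groups, 9 gave a share as large (one-sided exact permutation p = 0.129; the smallest p possible was 0.0143). Without Chrysin rat 3 it was 10.9% and without SU_HX rat 3 15.2%.

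The comparison of Chrysin with CTRL asked how far chrysin-dosed hearts stayed from untreated ones. Group means of natriuretic peptide, matrix and aryl hydrocarbon receptor target genes were higher in Chrysin than in CTRL rats, and those of fatty acid oxidation lower. Part of each list did not pass. Chrysin rats ran from 0.20 to 1.90 log2 from the CTRL mean for matrix and from -1.48 to -0.34 for fatty acid oxidation. Chrysin rat 3 lay nearest CTRL in both. By edgeR 581 genes rose and 488 fell (1069; 386 and 226, or 612, by at least 2-fold). The count moved with single libraries. It was 323, 365, 330 and 311 without CTRL rats 1 to 4, and 354, 321 and 303 without Chrysin rats 1, 2 and 4. Without SU_HX rat 1 or without Chrysin rat 3 it was 2092. SU_HX rat 1 is in neither group and enters only through the fit shared by all 12 libraries. Limma-voom called 1003, with 393 higher, a smaller share of higher calls. The authors' deposited table lists 1107 genes, 896 of them called here.

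Cyp1a1 stood at 113 ± 43.7 CPM (at least 743-fold higher than CTRL, adjusted p = 0.00437), Cyp1b1 at 404 ± 178 against 14.2 ± 3.33 CPM (adjusted p = 0.000195) and Nppa at 3656 ± 2912 against 16.7 ± 8.96 CPM (log2 7.77, SE 1.07, adjusted p = 0.00437). Thbs4 rose by 6.56 log2 (adjusted p = 0.00609; 0.168 by limma-voom), and Fgf23 stood at 1.95 ± 1.31 CPM (at least 12.8-fold higher, adjusted p = 0.00950). Adgra1, an adhesion G protein-coupled receptor, rose from a CTRL mean of 0.0480 CPM by 6.12 log2 (adjusted p = 0.0293), but was not called without any 1 of the CTRL rats or of Chrysin rats 1, 2 and 4 (0.0700 to 0.0969), nor by limma-voom (0.189) or without the filter on low counts (0.0507). The largest falls were those of Pcdh11x (ENSRNOG00000030330; chromosome X, 92596378 to 92691573, 3 exons), a protocadherin, from 10.2 ± 1.91 to 0.285 ± 0.389 CPM (log2 -5.32, adjusted p = 0.00437), and of Atp6ap1l (-3.42), Myoc (-3.35), Gabrb2 (-3.34) and Tnfrsf19 (-3.30), with adjusted p from 0.00590 to 0.00892. Of the other genes fixed in advance, Nppb (3.46 log2, adjusted p = 0.00437), Postn (4.69, 0.00757), Acta1 (2.57, 0.00643), Timp1 (2.84, 0.0121) and Myh7 (1.89, 0.0136) rose. Timp1 was not called by limma-voom (0.0643), nor Myh7 without CTRL rat 3 (0.0531). Myh6 stood at 11876 ± 15499 against 40499.9 ± 2549 CPM and did not pass (adjusted p = 0.143); without Chrysin rat 3 (0.00135), without this rat and SU_HX rat 1 (0.000445) or with voom quality weights (0.000721) it did. Atp2a2 (-0.95 log2, adjusted p = 0.160), Col1a1 (0.77, 0.302), Col3a1 (0.59, 0.411) and Vegfa (-0.05, 0.925) did not pass. Bmpr2 (0.43, 0.0932) passed without Chrysin rat 3 or SU_HX rat 1 (0.0366 to 0.0480) or by DESeq2 (0.0120), and Kdr (0.44, 0.291) without SU_HX rat 1 (0.0372). With only these 2 groups in the fit, with voom quality weights, or without SU_HX rat 1 and Chrysin rat 3, Atp2a2 passed (adjusted p from 0.00166 to 0.0246), as did Bmpr2 and Kdr; Col1a1 passed with the quality weights (0.0369).

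Camera called 20 lists (14 higher and 6 lower), and 0 with an estimated correlation; fry called 9 lists, 6 of them among these 20. Of 33 fatty acid oxidation genes 13 fell and 0 rose (23 fell adjusted over the list alone; camera adjusted p = 8.75e-17, and adjusted p = 0.468 with an estimated correlation), among them Cpt1a, which admits fatty acids to mitochondria (-0.90 log2, adjusted p = 0.00715), and Decr1 (-1.44, 0.00998). Of 24 cardiac stress genes 12 rose and 0 fell (17 rose adjusted over the list alone; camera adjusted p = 3.14e-16, and adjusted p = 0.468 with an estimated correlation). Of 43 matrix genes 20 rose and 0 fell (24 adjusted over the list alone; 2.76e-12, and adjusted p = 0.468 with an estimated correlation). Chrysin rat 3 lay nearest CTRL in its group for all 3 lists, at -0.34, 0.81 and 0.20 log2, with the other Chrysin rats at -1.48 to -1.12, 1.92 to 2.10 and 1.32 to 1.90. Of 8 aryl hydrocarbon receptor targets 4 rose and 0 fell (4 adjusted over the list alone; 1.95e-08, and adjusted p = 0.468 with an estimated correlation). They were Cyp1a1, Cyp1b1, Ahrr (5.42 log2, adjusted p = 0.00437) and Nqo1 (0.78, 0.0258), the last not called without CTRL rat 1, 2 or 4 or Chrysin rat 1, 2 or 4 (0.0545 to 0.0846). For these targets Chrysin rat 3 lay at 2.14 and the other Chrysin rats at 2.14 to 2.54.

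Of 18 complement genes 10 rose and 0 fell (13 adjusted over the list alone; 1.67e-09, and adjusted p = 0.468 with an estimated correlation), of 15 macrophage markers 7 rose and 0 fell (11 adjusted over the list alone; 4.81e-07, and adjusted p = 0.468 with an estimated correlation) and of 25 cytokine and chemokine genes 4 rose and 0 fell (8 adjusted over the list alone; 0.000660, and adjusted p = 0.468 with an estimated correlation). C1qc rose 3.20-fold (adjusted p = 0.00669) and Aif1 2.84-fold (0.00950). The cytokine list's 4 were Sele (4.07-fold, 0.00590), Csf1 (1.97-fold), the chemokine Cxcl16 (3.11-fold) and Il34 (1.80-fold), another growth factor of macrophages. Of 7 erythroid markers 6 rose (6 adjusted over the list alone; 9.31e-07, and adjusted p = 0.468 with an estimated correlation). Of 21 TGF-beta pathway genes 6 rose and 2 fell (9 and 2 adjusted over the list alone; 0.000755, and adjusted p = 0.527 with an estimated correlation), the ligand Tgfb2 9.74-fold higher (adjusted p = 0.00437) and the matricellular gene Ctgf 8.63-fold (0.00892). Tgfbr3 (-0.71 log2) and Smad3, a signal transducer (-0.55), fell. Of 19 matrix proteases and inhibitors 4 rose and 2 fell (8 and 2 adjusted over the list alone; 0.0109, and adjusted p = 0.584 with an estimated correlation), with Serpine2 4.19-fold higher (adjusted p = 0.00612), followed by Timp1, Adamts8 (2.92 log2) and Adamts1 (0.94). Adamts15 (-1.77 log2, 0.00765) and Adamts12 (-0.73) fell. Of 16 fibroblast markers 4 rose and 0 fell (6 adjusted over the list alone; 0.0108, and adjusted p = 0.538 with an estimated correlation), namely the transcription factor Meox1 (3.49-fold, adjusted p = 0.0124), Fap (2.97-fold), Pi16 (3.89-fold) and Mfap5 (2.36-fold). Of 21 ion channel genes 4 fell and 1, Cacna1g (6.61-fold, adjusted p = 0.00950), rose (4 and 1 adjusted over the list alone; 0.0192, and adjusted p = 0.529 with an estimated correlation). The potassium channels Kcnj3 (-1.78 log2), Kcnj5 (-0.84), Kcnh2 (-1.03) and Kcnd3 (-0.85) were those that fell. Many of these calls were lost when any 1 of several libraries was left out. Il34, Pi16, Mfap5, Kcnj5 and Kcnd3 were not called without any 1 of the CTRL rats or of Chrysin rats 1, 2 and 4 (adjusted p between 0.0516 and 0.123), and Kcnh2 was lost without SU_HX rat 4 as well (0.0527 to 0.132). Cxcl16 was not called without any 1 of the CTRL rats or Chrysin rat 2 or 4 (0.0535 to 0.0642), nor Smad3 without any 1 of the CTRL rats or Chrysin rat 1 or 4 (0.0554 to 0.104). Adamts1 needed CTRL rats 2, 3 and 4, Chrysin rats 1, 2 and 4 and SU_HX rat 4 (0.0505 to 0.118 without 1 of them), Adamts12 CTRL rats 1, 3 and 4 and Chrysin rats 1 and 2 (0.0650 to 0.0968), Kcnj3 CTRL rat 3 and Chrysin rats 1, 2 and 4 (0.0516 to 0.0605) and Fap CTRL rats 2 and 3 (0.0522 to 0.0537). By limma-voom Adamts8 (0.0566), Mfap5 (0.0532) and Pi16 (0.0695) were not called, nor Pi16 without the filter on low counts (0.0528).

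Ketone body and branched-chain amino acid genes had 4 that fell (7 adjusted over the list alone; 5.19e-06, and adjusted p = 0.529 with an estimated correlation) and contractile genes 2 (0 adjusted over the list alone; 0.00188, and adjusted p = 0.618 with an estimated correlation). The former were Acadsb, an acyl-CoA dehydrogenase (-0.89 log2), Bcat2 (-1.10), Pccb of propionyl-CoA carboxylase (-0.93) and Bckdk (-0.92), and the latter Cacna1c (-0.79) and Trdn (-1.08). Oxidative phosphorylation (3.36e-05, and adjusted p = 0.659 with an estimated correlation) and the tricarboxylic acid cycle (0.00186, and adjusted p = 0.643 with an estimated correlation) were called lower with 0 members passing by edgeR. Without SU_HX rat 1 or 2, Ndufs7 passed (0.0412 to 0.0463), without Chrysin rat 3, Ndufs7, Atp5c1 and Cox7b, of whose exon reads 71.4% were unique (0.0106 to 0.0472), and without SU_HX rat 1, Sdha and Suclg2 (0.0415 to 0.04996). DESeq2 called Ndufs7 (0.0392) and limma-voom 0. With only these 2 groups in the fit, without SU_HX rat 1 and Chrysin rat 3, or with voom quality weights, 15, 31 and 32 of the 49 oxidative phosphorylation genes passed, among them Atp5g1 (0.00101 to 0.0332). Of the 20 tricarboxylic acid cycle genes 7, 14 and 15 passed, among them Sdhd (0.00159 to 0.0172). Of 18 genes of the NRF2 antioxidant response 5 rose and 2 fell (7 and 2 adjusted over the list alone; 0.0315, and adjusted p = 0.529 with an estimated correlation; 0.0674 without CTRL rat 4). Risen members included Hmox1, heme oxygenase (6.36-fold, adjusted p = 0.00765), Gclc of glutathione synthesis (2.75-fold, 0.00643), Nqo1 (1.72-fold) and the ferritin light chain Ftl1 (2.04-fold), uncertain since only 12.6% of its exon reads were unique. The glutathione transferases Mgst1 (-0.93 log2) and Gsta4 (-1.25) fell. Of 20 p53 targets 4 rose and 2 fell (6 and 2 adjusted over the list alone; 0.0499, and adjusted p = 0.502 with an estimated correlation), with Sesn1 at -0.92 log2 (adjusted p = 0.0103) and the cell death gene Bcl2l11 at -0.55, and with Gadd45a 2.38-fold (0.0237), Plk2 2.41-fold and Pmaip1 2.84-fold among those higher. The list was not called without CTRL rat 1, Chrysin rat 1 or 2 or SU_HX rat 2 or 3 (adjusted p up to 0.0821). Ribosomal protein genes (1 of 61, Rpl3, rose; 1 adjusted over the list alone; 0.00963, and adjusted p = 0.765 with an estimated correlation) were not called without CTRL rat 4 (0.0535), nor cell cycle genes (0 of 32 passing by edgeR; 0.00252, and adjusted p = 0.654 with an estimated correlation) without Chrysin rat 3 (0.171) or this rat and SU_HX rat 1 (0.161); fry called neither (0.352 and 0.302). Of the cell cycle genes, Plk1 passed without SU_HX rat 1 (0.0480) and Anln without Chrysin rat 3 (0.0482) or by DESeq2 (0.0394); 29.2% of the exon reads of Anln were unique. With only these 2 groups in the fit Anln, Aurkb and Plk1 passed, without SU_HX rat 1 and Chrysin rat 3 Anln and Plk1, and with voom quality weights Anln, Aurkb, Foxm1, Kif23 and Plk1 (0.00700 to 0.04996). Several single genes also lost their call with a library left out. Bcat2, Pccb, Gsta4, Gadd45a and Pmaip1 were not called without any 1 of the CTRL rats or of Chrysin rats 1, 2 and 4 (adjusted p between 0.0521 and 0.122). Cacna1c and Trdn were lost without any of these or SU_HX rat 4 (0.0616 to 0.144), and Bckdk and Bcl2l11 without any of these or SU_HX rat 3 or 4 (0.0543 to 0.162). Acadsb needed CTRL rats 1, 3 and 4 and Chrysin rats 1 and 4 (0.0615 to 0.0757 without 1 of them), Nqo1 CTRL rats 1, 2 and 4 and Chrysin rats 1, 2 and 4 (0.0545 to 0.0846), Ftl1 CTRL rats 1 and 2 and Chrysin rats 1 and 4 (0.0527 to 0.0638), Plk2 CTRL rats 2, 3 and 4 and Chrysin rats 1 and 2 (0.0609 to 0.0790) and Rpl3 CTRL rat 3 (0.0504). Without the filter on low counts Cacna1c, Trdn, Bckdk and Bcl2l11 were not called (0.0574 to 0.0673), nor with all exon reads Cacna1c, Trdn and Bckdk (0.0502 to 0.0582). Bckdk was also lost with relative-log size factors (0.0544), Trdn with only these 2 groups in the fit (0.0534) and Pmaip1 by limma-voom (0.0621).

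Genes called against CTRL in both SU_HX and Chrysin in the same direction numbered 1022, with 565 higher and 457 lower. Independent lists of these sizes would share 92.8 and 71.8 genes. Groups simulated around the same means as CTRL, with the CTRL libraries drawn as well, shared 0. In those groups no gene was changed, so this 0 does not show how much overlap the shared CTRL rats create. The simulation also left out the correlation between genes. With the 4 CTRL rats split between the comparisons in 1 fit, Chrysin had 2 to 6 calls over the 6 splits, and each of them was shared with the 1499 to 1838 SU_HX calls, where independent lists would share 0.122 to 0.453. With each comparison fitted alone on its 6 libraries, 6 to 14 of 11 to 34 Chrysin calls were shared with 531 to 661 SU_HX calls, against 0.258 to 0.910 by independent lists.

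The authors' deposited table lists 2 genes at an adjusted p under 0.05 between Chrysin and SU_HX, Cttn_1 (ENSRNOG00000050994; chromosome 1, 215255381 to 215290845, 21 exons) with a signed fold of -2.43 (adjusted p = 0.00378) and Hba-a3 (ENSRNOG00000045989; chromosome 10, 15577249 to 15577977, 3 exons) with -11.6 (adjusted p = 0.0437). Neither passed here (0.461 and 0.557 by edgeR). The table holds a second cortactin copy, Cttn_2 (ENSRNOG00000047280; chromosome 1, 217602698 to 217638152, 24 exons). Only 2 of 3132 and 5 of 1569 exon reads of Cttn_1 and Cttn_2 were unique, so the division of reads between them is uncertain. The share of Cttn_1 in both copies was 88.2 ± 9.25% in SU_HX, 43.2 ± 11.2% in Chrysin and 75.9 ± 17.9% in CTRL. A test of this share in the same rats is not independent evidence, since Cttn_1 was singled out by its low p in them. Summed over both copies, the log2 change from SU_HX to Chrysin was -0.29 (SE 0.13, adjusted p = 0.554).

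**Figure D3:**
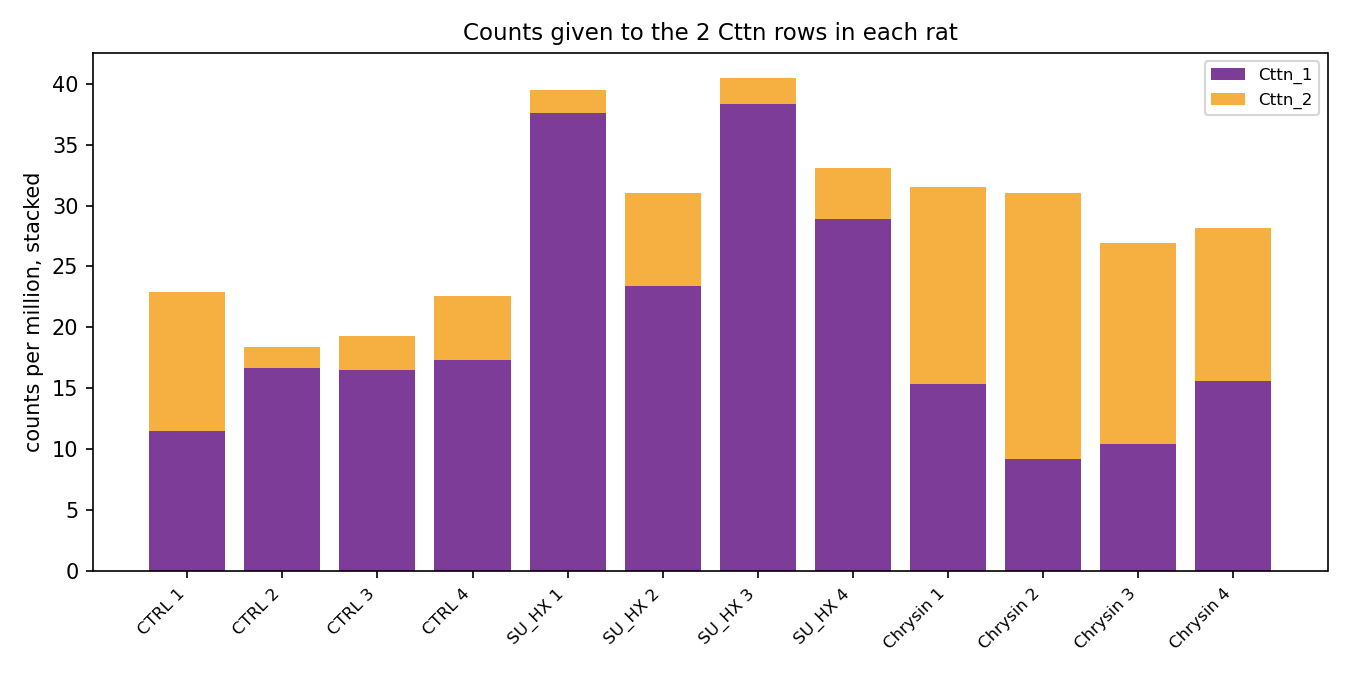
Level of the 2 cortactin copies in each of the 12 rats, in CPM, stacked as bars from 0 by copy and ordered by group. Both copies together averaged 36.0 CPM in SU_HX and 29.4 CPM in Chrysin, while Cttn_1 alone averaged 32.0 and 12.6 CPM.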

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

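The values named first here were picked by a test for a library far from the other 3 of its group. The tests in this part, the counts of other splits included, were all set out after the result was seen. Some were revised once their values were known, and that for Hba-a3 was replaced when the first version proved to rest on Chrysin rat 1.

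In all, 48 of 561 groups of 4 had such a library, where chance gives about 1 in 20 (28.1) for independent, normally distributed values. Of these, 24 were Chrysin rat 3, 6 SU_HX rat 1 and 2 SU_HX rat 3. Genes move together within a rat, so these flags are not separate events and the excess is no test. Any count is flagged where the other rats of a group are at 0, as for Adgra1 and Sftpa1 in CTRL rat 2. Over all 127 genes that the rule takes, 42 of 381 groups had one, over the 102 of these in the text 34 of 306, and over the 53 named after their values were seen 8 of 159. Chrysin rat 3 had the lowest total count of its group, 3997306. In CPM, this rat stood above the other Chrysin rats for Atp5c1 (633), Atp5g1 (703), Bckdk (131), Crybb1 (4.12), Cxcl11 (3.02), Decr1 (70.2), Dhrs7c (55.7), Gabrb2 (5.49), Hadh (327), Myh6 (35113), Myo16 (9.88), Sdhd (349) and Sesn1 (93.6). It stood below them for Bmpr2 (236), Cacna1g (27.7), Gclc (27.2), Hmox1 (14.3), Lama5 (212), Ndrg1 (24.97) and Nr4a3 (4.66). It also stood below them for the means of 3 lists, in log2 from CTRL: cardiac stress (0.81), fibroblast markers (0.0305) and p53 targets (0.0679).

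SU_HX rat 1 stood above its group for Cyp1a1 (268 CPM), Acvr2b (5.10), Egr3 (21.3), Foxm1 (11.6), Pcdh11x (1.62) and Vegfa (985), and SU_HX rat 3 for C1qtnf3 (31.3) and Ftl1 (26.1). SU_HX rat 2 was high for Adrb1 (11.5) and low for Flt4 (48.7). In Chrysin rat 1 the alpha-globin copies Hba-a2_1 and Hba-a2_2 stood at 1825 and 3014 CPM, against 279 to 513 and 616 to 966 in the other 3; Chrysin rat 2 had the lowest median intron share of a gene (41.1%). Among CTRL rats, rat 1 was low for Cttn_1 (11.5 CPM), rat 2 high for Adgra1 (0.192) and Sftpa1 (0.959), rat 3 high for Adra1b (82.6), Atp2a2 (17276) and Ppara (75.5), and rat 4 low for Hadh (461) and Trdn (145) and high for Aurkb (2.98), Lamb1 (587) and the TGF-beta list (0.13 log2). Outside the gene counts, reads over the mitochondrial ribosomal RNA positions, which the table lists without exons, made up 33.1% of unique reads in SU_HX rat 1, 25.8% in SU_HX rat 3, 22.0% in Chrysin rat 3 and 19.4% in SU_HX rat 4, above the 9.03 to 18.0% of the CTRL rats.

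Within its group, Chrysin rat 3 lay nearest the CTRL rats for stress, matrix and metabolic genes. Its mean lay within the CTRL range for oxidative phosphorylation (0.03 log2 from the CTRL mean) and outside it for matrix (0.20, highest CTRL rat 0.13), fatty acid oxidation (-0.34, lowest -0.08) and stress genes (0.81, highest 0.04). A CTRL library under the wrong label is argued against by the aryl hydrocarbon receptor targets, which lay 2.14 log2 above the CTRL mean, where the highest CTRL rat lay at 0.196. RNA of a CTRL rat mixed in at 1 share for every gene is argued against less firmly. The share was set at the median of the rise seen in 526 other risen genes (13.8%). Over the 5 targets that rose in SU_HX, the affected RNA would then need a median of 2.05 times the highest level in the other 7 model rats. By target this was 4.72 for Cyp1a1, 2.61 for Ahrr, 2.05 for Cyp1b1, 1.97 for Nqo1 and 0.89 for Ahr. At the upper quartile of the shares (28.0%) the median was 1.23 times, with Cyp1b1 at 1.02. The 526 genes were chosen partly by a mean at least 2-fold over CTRL in the other Chrysin rats. That choice, which the targets did not have to pass, can lower the share and raise the level needed. Less change in that rat's heart, and tissue taken from another part of the heart, remain open and were not tested.

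SU_HX rat 1 differed from the other SU_HX rats in many genes. Its deviation rose with the intron share of a gene (Spearman rho 0.36 across 10692 genes, which are not independent replicates). The others had -0.158, -0.0766 and -0.190. Each deviation was taken from the mean of the other SU_HX rats, so a positive value in 1 rat pushes the rest down. Those negative values are therefore no separate evidence. More unspliced RNA in that library is a candidate explanation for part of the difference. Fewer heart muscle cells with no other change is argued against, since markers of other cell types moved apart by 2.39 log2, from +1.36 for endothelial to -1.03 for lymphatic markers. A larger endothelial share in that sample stays open and was not tested.

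The authors' table lists Cttn_1 and Hba-a3 as lower in Chrysin than in SU_HX. For Cttn_1, reads shared between near-identical copies may account for the difference: summed over both copies the log2 change was -0.29 (SE 0.13), against -1.33 for Cttn_1 and 2.05 for Cttn_2. For Hba-a3, the Hba-a2 copies summed changed by -0.26 log2 (SE 0.59) and Hba-a3 by -3.55 (SE 0.81), but without Chrysin rat 1 the values were -1.13 (SE 0.51) and -3.33 (SE 0.92). Within a rat, Hba-a3 per 1000 counts of Hba-a2 ran from 0 to 1.29 in Chrysin and from 1.57 to 4.21 in SU_HX rats. The mean difference was -2.54 (-2.45 without Chrysin rat 1, and -2.97 to -2.09 with each library left out). CTRL rats, with few counts, ran from 0 to 10.2. Chrysin rats 1 to 4 also had few counts of Hba-a3 (2, 0, 0 and 12). Hba-a3 was singled out by its low value in these rats, so the ratio is not independent evidence. It does not decide whether less blood was the whole cause. A sequence difference between rats of the groups was not tested, and what set Hba-a3 lower stays open.

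Of the 35 splits of the 8 libraries, only that by the labels gave as many as the 3776 genes called in SU_HX. The highest other split gave 0. The same held in Chrysin against CTRL (1 of 35, with 1069 against 1). A share of 1 of 35 is the smallest this test can give, and splits that mix the groups widen the spread within them. Chance in how the rats were grouped was thus made less likely but not excluded. For Chrysin against SU_HX, with 0 genes called, all 35 splits reach that count by construction and it decides nothing about chance; 3 of the other splits called any gene, at most 55. Chance was not excluded for the lists called by camera: 10 of 35 splits gave at least the 20 of SU_HX against CTRL (highest other 24), 13 of 35 at least the 19 of Chrysin against SU_HX (26) and 8 of 35 at least the 20 of Chrysin against CTRL (24). Splits that exchange only 1 rat per group keep part of the difference between the groups, and the count of called lists need not fall with it. Camera's counts of lists therefore cannot decide whether chance made these calls.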

How the results depend on the processing

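Leaving out SU_HX rat 1 and Chrysin rat 3 together, the quality weights, the unique and all exon reads and the summed copies were chosen after the result was seen; the other settings were planned. SU_HX against CTRL had 3776 genes, 1900 with a fold of at least 2, and 2486 (without SU_HX rat 3) to 4780 (without SU_HX rat 2) with each library left out. Chrysin against SU_HX had 0 genes under all settings but DESeq2 (2, which were also the 2 called in opposite directions), among 1002 at an unadjusted p under 0.05 in edgeR. Chrysin against CTRL had 1069, against 1733 with DESeq2, 2599 with only the groups compared and 3564 without SU_HX rat 1 and Chrysin rat 3. It had 4589 with quality weights and 612 with a fold of at least 2. With each library left out it had 303 (without Chrysin rat 4) to 2092 (without SU_HX rat 1, or without Chrysin rat 3). SU_HX rat 1 is in neither of these groups and enters the count only through the filter, scaling and spread shared by the fit. Its quality weight, 0.137, was the lowest of the 12 libraries. Which part of the fit it acted on was not separated, and the cause of the other shifts was not tested. Rat numbers did not pair the libraries (12 correlations from -0.382 to 0.0745, 0 of 12 libraries closest to their own number); with the replicate block 3242, 0 and 624 genes and 20, 20 and 21 lists were called. With that block the calls of Acvr2b, Bmpr2, Col1a1, Col3a1, Col4a2, Kdr, Mbp, Ndrg1, Rgs5 and the cell cycle list in SU_HX against CTRL (adjusted p from 0.0501 to 0.0788), and of Bckdk, Bcl2l11, Cacna1c, Il34, Kcnd3, Kcnh2, Mfap5, Nqo1, Pi16 and Trdn in Chrysin against CTRL (0.0510 to 0.0820), were absent. The called lists, 20, 19 and 20, were 0, 0 and 0 with an estimated correlation, 25, 0 and 9 by fry, and 20, 23 and 22 without SU_HX rat 1 and Chrysin rat 3. Fatty acid oxidation in Chrysin against SU_HX turned its sign without these 2 libraries (adjusted p = 0.441). The share opposed of 27.1% lay between 10.9 (without Chrysin rat 3) and 37.1% (without Chrysin rat 4) with each library left out, and at 9.08% without both. Values of named genes kept direction and side of the threshold in 2286, 1427 and 1664 settings, lost the call in 148, 0 and 219, gained it in 7, 2 and 46 and changed sign without a call in either setting in 3, 47 and 2 for the 3 comparisons in the order above; 0 called values changed sign. Those signs were of Vegfa in all 3 and, in Chrysin against SU_HX, of Acta1, Bmpr2, Col1a1, Cyp1a1, Cyp1b1, Kdr, Myh7, Nppa and Nppb. Lists kept theirs in 307, 262 and 297 and lost it in 33, 60 and 43. Pseudocounts were not run, and the opposed share has no block since it comes from no fit. With 4 libraries per group, 2-fold changes were recovered at 41.8 to 47.8% on simulated data, so smaller changes may be missed. Recovery in the real libraries may be lower, since the simulated genes were independent and shared 1 spread across groups.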

Other observations

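The counts and tests of lists in this part were planned, and the choice of which to describe came after their values were seen. Several lists held members that changed in SU_HX against CTRL without a call by camera. Of 9 Schwann cell and neuronal markers 4 rose and 0 fell (4 adjusted over the list alone; camera adjusted p = 0.0700, adjusted p = 0.468 with an estimated correlation, fry adjusted p = 0.0130). They were the adhesion molecule Ncam1 (4.18 log2, adjusted p = 0.00123), the neuronal hydrolase Uchl1 (3.98; 0.0678 by limma-voom), the glial filament Gfap (2.42) and the myelin gene Mbp (0.87). Gfap was not called without CTRL rat 1 or 2 or SU_HX rat 3 (adjusted p from 0.0547 to 0.0624), nor Mbp without CTRL rat 1, 3 or 4 or SU_HX rat 3 (0.0775 to 0.0975), without the filter on low counts (0.0525) or with only these 2 groups in the fit (0.0505). Of 24 vasoactive and renin-angiotensin genes, which set vessel tone, 8 rose and 4 fell (9 and 4 adjusted over the list alone; camera 0.0808, adjusted p = 0.529 with an estimated correlation, fry 0.0473). The fallen ones were the adrenergic receptors Adra1b (-1.89 log2), Adra1a (-1.39) and Adrb1 (-1.04; 0.0518 without SU_HX rat 3) and Corin, the protease that activates atrial natriuretic peptide (-1.04). Corin was not called without CTRL rat 1, 3 or 4 or SU_HX rat 1 or 3 (0.0518 to 0.0971), nor without SU_HX rat 1 and Chrysin rat 3 (0.0655).

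Of 10 VEGF ligands and receptors 4 rose and 1 fell (5 and 1 adjusted over the list alone; camera 0.128, adjusted p = 0.538 with an estimated correlation, fry 0.0487). Besides Kdr, the lymphatic receptor Flt4 (1.23 log2, adjusted p = 0.00151) and its ligands Vegfd (2.29) and Vegfc (1.11) rose, and Vegfb fell (-1.21). Kdr was not called without any 1 of the CTRL rats, Chrysin rat 1 or 2 or SU_HX rat 1 (adjusted p from 0.0570 to 0.102), nor by limma-voom, without the filter, with only these 2 groups in the fit, with voom quality weights or without SU_HX rat 1 and Chrysin rat 3 (up to 0.0820). Vegfc was not called without CTRL rat 2, 3 or 4 or SU_HX rat 1 or 3 (0.0506 to 0.0715) and Vegfb not without SU_HX rat 3 (0.0526). BMP pathway genes had 8 of 19 rising and 2 falling (8 and 2 adjusted over the list alone; camera 0.134, adjusted p = 0.589 with an estimated correlation, fry 0.0624). Those falling were the transducer Smad9 (-1.07 log2), of whose exon reads 76.4% were unique, and the receptor Acvr2b (-1.08). Smad9 was not called without CTRL rat 1, 2 or 3 or SU_HX rat 3 (0.0517 to 0.0770), nor Acvr2b without any 1 of the CTRL rats, Chrysin rat 1 or 2 or SU_HX rat 2, 3 or 4 (0.0541 to 0.102) or with only these 2 groups in the fit (0.0727). Of 14 smooth muscle and pericyte markers 4 rose and 0 fell (4 adjusted over the list alone; camera 0.0542, adjusted p = 0.538 with an estimated correlation, fry 0.0497), with log2 values of 0.93 for Cald1, 1.11 for Pdgfrb, 0.80 for Cspg4 and 0.59 for Rgs5. Rgs5 was not called without any 1 of the CTRL rats, Chrysin rat 1 or 2 or SU_HX rat 1, 3 or 4 (0.0534 to 0.0994), nor without the filter, with only these 2 groups in the fit or without SU_HX rat 1 and Chrysin rat 3 (up to 0.0807). Endothelial markers had 1 of 16 that fell, the peptide gene Apln (-2.19 log2, adjusted p = 0.00250), and 0 that rose (camera 0.321, adjusted p = 0.861 with an estimated correlation, fry 0.508). Their mean in SU_HX rat 1 lay 1.24 log2 above CTRL, with the other 3 SU_HX rats at -0.30 to 0.06. Of 24 targets of the hypoxia-inducible factors 5 rose and 2 fell (6 and 2 adjusted over the list alone; camera adjusted p = 0.354, adjusted p = 0.552 with an estimated correlation, fry 0.0651). The risen ones were the collagen hydroxylase P4ha1 (1.59 log2), Hmox1 (2.87), Angptl4 (2.96; 0.0649 by limma-voom), the lactate transporter Slc16a3 (1.84) and Ndrg1 (0.94). The oxygen sensor Egln1 (-1.08) and the kinase Pdk1, which limits pyruvate oxidation (-1.37), fell. Calls were lost for Slc16a3 without CTRL rat 2 or 3 or SU_HX rat 3 (adjusted p from 0.0533 to 0.0590) or by limma-voom (0.0870), for Ndrg1 without CTRL rat 1, 3 or 4 or SU_HX rat 3 (0.0534 to 0.0853) and for Pdk1 without any 1 of the CTRL rats or SU_HX rat 3 (0.0529 to 0.0962) or with only these 2 groups in the fit (0.0639). Of 20 p53 targets 8 rose and 2, Sesn1 (-1.57 log2) and Bcl2l11 (-0.70), fell (10 and 2 adjusted over the list alone; camera 0.0533, adjusted p = 0.502 with an estimated correlation, fry 0.0204). All 13 mitochondrially encoded genes stayed short of the threshold in edgeR, while 35 of 49 nuclear genes of the same complexes fell. The mean of the mitochondrially encoded list lay 0.39 log2 above CTRL in SU_HX. Its SD among CTRL rats was 0.70, against 0.117 for the nuclear list, so changes of these genes may be missed.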
